A study of Caenorhabditis elegans with 15 samples.

How the data were processed

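RNA from 15 embryo samples, 3 at each of 5 time points, was measured on 1-colour Affymetrix C. elegans arrays from biotin-labelled RNA, per the labels' protocols. The authors' deposited table held 1 log2 expression value per probe set and array for 22625 probe sets, made with RMA per the submitters' processing notes, with no version given. RMA corrects the background, normalizes between arrays and summarises the probes of a probe set. The log2 scale was read from the values, which ran from 1.78 to 14.2. The medians of the deposited columns were close, from 3.17 to 3.42, while their 90th percentiles ran from 6.23 (1 h B) to 7.45 (0 h C). Detection calls and scanner files were not used here. RMA compresses low values, so folds of genes near background are uncertain, and the highest value of the 15 background control probe sets, 3.22, served as a mark of background. All columns were assigned to samples by name, and 0 were left unassigned.

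Arrays were grouped by the hour in their titles. The titles of 2 arrays, 1 h B and 1 h C, conflict with their time tags of 2 h and 3 h, while the series' design text gives 3 samples per time, so both groupings were run. By the tags, or without both arrays, 1 h A is the only 1 h array. The labels call the samples of a time independent without saying whether they came from separate mothers or days, so p-values measure the spread between these samples, which may be technical. No array pair was identical, and the replicate letters were tried as a block.

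The 77 Affymetrix control probe sets were left out of the tests, leaving 22548. Of these 20810 had 1 gene symbol, 843 several and 895 none in the platform annotation, and 20745 of the first group were updated through Entrez identifiers to the WBcel235 gene table. Another 44 had their single symbol repeated in the annotation. No gene was named from a probe set with several symbols. A gene was represented by the probe set with the highest mean over the 15 arrays among those with its symbol alone, which gave 17138 genes, 2998 of them with more than 1 such probe set. Other probe sets gave the opposite sign past the threshold for eef-1A.2, dsh-1, zfp-3, polq-1 and F23B12.4 between 0 h and 4 h and for kin-33 between 1 h and 2 h. Among called list members, another probe set missed the threshold in at least 1 named comparison for abu-14, ced-2, cdk-4, cya-1, cyb-2.2, die-1, dyf-2, fbn-1, hsp-6, hsp-60, lam-1, lam-3, mex-1, mls-2, noah-1, ost-1, par-2, ptr-2, sqt-3 and tbx-2. The annotation names no genome build, so no coordinates are given.

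All 5 times entered a single linear model in limma 3.58.1 under R 4.3.3 (lmFit and eBayes), in which they share an estimate of the spread. The comparisons were 4 h against 0 h and each step, with an F test over all times, and a call needed a Benjamini-Hochberg adjusted p under 0.05 over all probe sets. A transient transcript was above 0 h at 1, 2 or 3 h and lower at 4 h than at that time, each past the threshold. Adjusted p-values in all parts are those of limma. The median standard error of a difference was 0.19 and that of the 90th percentile 0.44 on the log2 scale. Before the data were examined, 17 gene lists, the 3 injected genes, the tests, the rule for naming genes and most alternatives were fixed. The lists cover regulators and structural genes of mesoderm and pharynx, other tissues and lineages, maternal transcripts, cell cycle, stress, apoptosis, adult and sperm transcripts, and ribosomal proteins. Each was tested for 4 h against 0 h with limma's camera (preset correlation 0.01 between genes), adjusted over the 17 lists, and again with an estimated correlation. The calls of the mesoderm and pharynx regulators, maternal and ribosomal protein lists held with the estimated correlation, and those of the neuron and basement membrane lists did not. Members were also counted with p adjusted over the list alone.

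Named were the 12 largest rises and 12 largest falls between 0 h and 4 h, the 6 largest of each in every step and 6 per transient time, among genes past the threshold. For 4 h against 0 h and for the steps all 3 arrays of a time had to lie beyond all 3 of the other. Genes with a cosmid-style name counted in that ranking and are given only in part. The 3 injected genes and any member of the fixed lists could also be named, and which list members are named was chosen after their values were seen. Differences are log2 values with the standard error (SE) of the model, and levels are means with the SD of 3 arrays.

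The procedure was tested on simulated data with the real means and spreads. For 4 h against 0 h with 22548 probe sets, 68%, 84%, 94% and 100% of 50 probe sets changed by 1, 2, 3 and 4 log2 units were recovered, with 8 false calls. With no change, 0 transient transcripts were called by limma at 1, 2 or 3 h, as needing calls in both comparisons leaves almost none by construction. The simulated noise was independent between probe sets and few of them were changed, whereas 16.7% were called here for 4 h against 0 h. These figures therefore describe the simulated setting and not the real calls. The alternatives were the replicate letter as a block, the grouping by time tags, both arrays of conflicting tag left out, the upper part of the probe sets by mean, and no probe sets whose name marks possible cross-hybridisation. Others were a trended robust eBayes, array weights, arrays centred on ribosomal protein genes, Affymetrix controls or the array median, limma's treat at 1.5-fold, an adjusted p under 0.01, each array left out in turn, the mean of a gene's probe sets, and the estimated correlation. Chosen after seeing the data were arrays centred on the 18 hybridisation control probe sets, the leaving out of array 1 h B in comparisons without 1 h, and the list counts without 1 h B.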

Results

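Wild-type C. elegans hermaphrodites (strain N2) received dsRNA against mex-1, lit-1 and pal-1 by injection, which lowers the matching transcripts by RNA interference. Embryos at the 2- to 4-cell stage were dissected from them, and total RNA was taken after 0, 1, 2, 3 or 4 h of further development. As background, mex-1 encodes a maternal zinc-finger protein whose loss gives descendants of the anterior blastomere AB the fate of the blastomere MS, a founder of pharynx and body wall muscle. lit-1 encodes a kinase that acts with Wnt signalling to make the gut founder E differ from its sister MS, and pal-1 a Caudal homeobox protein that specifies the C and D lineages. The series title names the control of fate in the MS lineage, and the time course follows transcript levels as such embryos develop. Each time point had 3 Affymetrix arrays, named A, B and C here, 15 in all, with 22548 probe sets tested for 17138 genes. The array median lay between 3.17 and 3.42 on the log2 scale, and the number of arrays limits the precision.

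Across probe sets, which are not independent replicates, the mean correlation within a time was 0.973 at 0 h, 0.937 at 1 h, 0.974 at 2 h, 0.971 at 3 h and 0.966 at 4 h, against 0.815 between 0 h and 4 h arrays. Between neighbouring times it was 0.885 for 0 h and 1 h, 0.894 for 1 h and 2 h, 0.945 for 2 h and 3 h and 0.956 for 3 h and 4 h, the last 2 above the mean within 1 h. Some single pairs of different times, such as 3 h C with 4 h A at 0.967, lay above pairs of 1 time, such as 4 h A with 4 h C at 0.962. Array 1 h B stood apart from the other 1 h arrays, with a correlation as low as 0.914 where 1 h A and 1 h C reached 0.981. Its vit-4 value, a yolk protein transcript of the adult gut, was 8.58 against 3.06 on 1 h A and 3.15 on 1 h C. Its hybridisation controls, bacterial and phage RNAs added before hybridisation, averaged 11.70 against 8.64 to 11.099 on the other 14 arrays. The arrays named 1 h B and 1 h C carry time tags of 2 h and 3 h in the labels, which would leave 1 h A alone at 1 h, and the titles were followed. Over the whole course 4630 probe sets (20.5%) changed with time by limma's F test, against 2193 when those 2 arrays were placed by their tags.

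**Figure D1:**
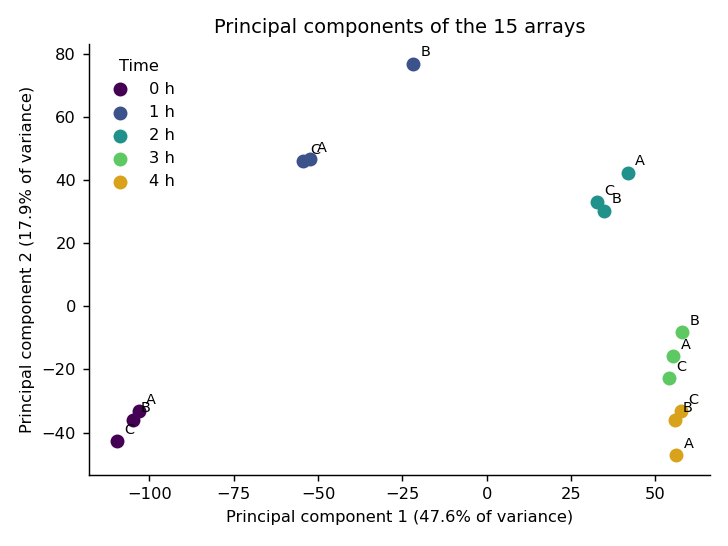
Each point is 1 of the 15 arrays on the first and second principal components of 22548 probe sets (log2), which held 47.6% and 17.9% of the variance, coloured by time point. The 0 h arrays lie at the low end of the first component, and 1 h B lies apart from 1 h A and 1 h C.

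The 3 injected genes showed no called change in any of the 5 comparisons given in full. mex-1 measured 4.63 ± 0.68 at 0 h and 5.65 ± 0.91 at 4 h (log2, SD, n = 3), lit-1 3.84 ± 0.13 and 4.33 ± 0.29, and pal-1 6.51 ± 1.25 and 7.13 ± 1.21. The 4 h minus 0 h differences were 1.02 for mex-1, 0.49 for lit-1 and 0.62 for pal-1, and limma's count past the threshold was 0 of 3. The pal-1 difference ran from -0.091 without 0 h C to 1.26 without 4 h A. At an unadjusted p under 0.05 that count was 1, and adjusted over the list alone it was also 1. At 2 h, where mex-1, lit-1 and pal-1 read 6.60, 4.34 and 8.63, they were 1.97, 0.50 and 2.12 above 0 h, and limma called 0 of 3 over all genes and 3 of 3 adjusted over the list alone and at an unadjusted p under 0.05. Other probe sets gave 0.43 and 2.34 for pal-1, 0.39 and 0.069 for lit-1 and 0.33 for mex-1 at 2 h, and none of them passed the threshold. mex-1 was 2.1 ± 0.62 (SE) higher at 3 h than at 0 h (adjusted p = 0.036), a call that ended without 0 h A, 0 h B or any 1 of the 3 h arrays, with the arrays placed by their tags, and with arrays centred on their median, on ribosomal protein genes or on the hybridisation controls. The other mex-1 probe set, with a mean within background at every time, changed by 0.01 at 3 h (adjusted p = 0.99). Untreated embryos were not analysed here, so these levels do not measure the effect of the dsRNA.

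Between 0 h and 4 h, transcripts of regulators of mesoderm and pharynx rose and maternal transcripts of the oocyte and early embryo fell. The forkhead gene let-381 rose from 3.16 ± 0.14 to 10.21 ± 0.31 (log2, SD, n = 3), a 133-fold difference, and the T-box gene tbx-7 rose by 7.58 ± 0.33 (SE). Larger still were the rises of his-24, a linker histone, by 8.51 ± 0.45 (363-fold), and hmg-11, a high mobility group protein, by 8.41 ± 0.16 (340-fold). The largest fall was that of sip-1, a small heat shock protein of early embryos, from 14.01 ± 0.04 to 5.23 ± 1.10 (440-fold lower, adjusted p = 1.2e-07). The eggshell proteoglycan genes cpg-3 and cpg-2 fell by 8.17 and 7.79 on the log2 scale, the Y-box genes cey-3 and cey-2 fell by 7.87 and fell by 7.49 on that scale, and nos-2, a Nanos homologue of the germ line, by 7.06. rmd-1, clec-87 and the glycogenin gene gyg-2 fell by 7.88, 7.44 and 7.07 on the log2 scale, and fbxc-34 and clec-266 rose by 7.66 and 7.25. In each of these genes all 3 arrays at 4 h lay beyond all 3 at 0 h. In total 1603 probe sets were higher at 4 h and 2157 lower by limma (1213 and 1664 genes), of which 1159 and 1908 differed at least 2-fold.

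Of the 22 measured regulators of mesoderm and pharynx, 10 rose, and 13 did when adjusted over the list alone (mean difference 1.94, camera adjusted p = 5.5e-07, and adjusted p = 0.029 with an estimated correlation). Beside let-381 these were hnd-1, a Hand homologue, by 6.51 ± 0.33 (SE), ceh-34 and ceh-32, Six-family homeobox genes, by 5.37 and 2.32, and ceh-22, an NK-2 homeobox gene of pharyngeal muscle, by 4.12. The others were the forkhead gene fkh-2 by 3.91, eya-1 by 3.34, unc-39 by 2.30, tbx-2 by 1.56 and mls-2 by 1.29. The muscle regulators hlh-1, a MyoD homologue, and unc-120 differed by 0.72 (adjusted p = 0.19) and 0.76 (adjusted p = 0.086), and the pharynx regulator pha-4 by 1.81 (adjusted p = 0.12), and none of these passed the test.

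Of 38 body wall muscle genes, act-4 (2.69 ± 0.44, SE), unc-97 (2.24) and unc-95 (0.48) rose and act-3 fell by 2.41 on the log2 scale. Adjusted over the list alone 2 were higher and 1 lower, and the values of the actin genes, which are close copies, are uncertain. The myosin genes myo-3 and unc-54 differed by 0.04 and 0.28, and myo-2 of the pharynx by 0.19. limma called 0 of 22 pharynx structure genes, over all genes and adjusted over the list alone, with 1 higher at an unadjusted p under 0.05, and 9 of the 22 stayed at or below the highest background control at every time. Of 12 genes of other mesoderm cup-5 fell by 2.02 on the log2 scale, also when adjusted over the list alone. That list's mean (-0.08) and median (0.08) differ in sign. Of 14 basement membrane genes 5 rose, and the same number adjusted over the list alone, led by the laminin genes lam-3 (4.81 ± 0.30, SE) and epi-1 (4.37 ± 0.34), with dgn-1 (0.74), lam-1 (0.66) and ost-1 (0.56). The camera test of that list gave an adjusted p = 0.019, and adjusted p = 0.21 with an estimated correlation, and 0.0035 to 0.21 over 22 settings. Its mean of 0.88 became -0.43 with arrays centred on ribosomal protein genes and -0.08 with arrays centred on the hybridisation controls. Both scalings move all genes of an array alike. The list still passed camera in both (adjusted p = 0.048 and 0.0086). Camera compares a list with the other genes, which are shifted too, so passing there is weak support.

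Of 40 genes of the neuron list 10 rose and 1 fell, and adjusted over the list alone the counts were the same. The proneural genes hlh-14 and lin-32 rose by 4.67 ± 0.39 and 4.02 ± 0.27 (SE), hlh-2 and hlh-3 by 2.15 each, cnd-1 by 1.98 and ngn-1 by 1.40. The homeobox genes ceh-36 and unc-30 rose by 2.90 and 1.56, unc-119 by 1.73, and unc-76 fell by 1.04 on the log2 scale. The list's mean of 0.76 passed the camera test (adjusted p = 0.00055, adjusted p = 0.21 with an estimated correlation, and 5.7e-06 to 0.21 over 22 settings). It became -0.55 and -0.20 with the same 2 scalings. The list still passed camera in both (adjusted p = 5.7e-06 and 0.00011), which again is weak support. Of 26 cilium genes dyf-2 (0.82) and osm-12 (0.47) rose, with 1 higher adjusted over the list alone and 4 without 1 h B.

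Of 26 epidermal genes the collagen genes dpy-17 (4.29 ± 0.48, SE) and sqt-3 (1.36) and noah-1 (0.91) rose, while ptr-2, lin-26 and noah-2 fell by 4.66, 1.85 and 0.60 on the log2 scale. Adjusted over the list alone 4 were higher and 3 lower, without 1 h B 5 were higher, and the ptr-2 probe set that should not cross-hybridise gave 0.80. Of 11 regulators of the C and D lineages the Hox gene ceh-13 (3.78 ± 0.22) and scrt-1 (0.75) rose and the T-box gene tbx-9 fell by 3.56 on the log2 scale, with 3 higher and 1 lower adjusted over the list alone. Of 15 Notch and AB lineage regulators ceh-36, die-1 (1.65) and unc-130 (1.17) rose and the Notch receptor gene glp-1 fell by 2.97 on the log2 scale, with 3 higher and 2 lower adjusted over the list alone. limma called 0 of 21 endoderm genes, over all genes and adjusted over the list alone, with 1 higher at an unadjusted p under 0.05 and 1 higher past the threshold without 1 h B. The gut regulator elt-2 differed by 0.49 (adjusted p = 0.099), and the list's mean (0.03) and its camera direction, which was down, differ in sign.

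Of 52 maternal genes 37 fell, and 38 adjusted over the list alone (mean difference -3.04, camera adjusted p = 1e-28, and adjusted p = 0.029 with an estimated correlation). Next to cpg-2, cey-2 and nos-2 the eggshell genes cbd-1 and cpg-1 fell by 6.66 and 6.49 on the log2 scale, and pos-1, a zinc-finger regulator of maternal RNA, by 6.35. Of 62 ribosomal protein genes 55 rose, and 56 adjusted over the list alone (mean 1.31, camera adjusted p = 6.2e-30, and adjusted p = 0.037 with an estimated correlation). The gene rpl-11.2 rose by 2.94 ± 0.25 (SE) and its close copy rpl-11.1 fell by 1.97 on the log2 scale. Of 43 cell cycle genes 5 rose and 8 fell, with 8 and 14 adjusted over the list alone and 13 lower without 1 h B. cki-1, an inhibitor of cyclin-dependent kinases, rose by 4.57 ± 0.31, the cyclin A gene cya-1 by 2.35, knl-2 by 2.29, cdk-4 by 1.48 and cdk-2 by 0.66. The B-type cyclin genes cyb-2.1 and cyb-2.2, which are close copies, fell by 6.30 and 6.07 on the log2 scale, cdc-25.1 by 3.12 and mcm-6 by 2.96. The cell cycle list's mean of -0.54 missed the camera threshold (adjusted p = 0.085) and passed it with arrays placed by their tags (adjusted p = 0.036), with arrays centred on the Affymetrix controls (adjusted p = 0.014) and without 0 h B, 4 h A or 4 h B.

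The chaperone genes hsp-1, hsp-4, hsp-60 and hsp-6 fell by 4.58, 3.33, 1.68 and 1.45 on the log2 scale, 4 of the 14 stress genes measured and the same number adjusted over the list alone. The stress list's mean (-0.68) and median (0.02) differ in sign. Of 18 apoptosis genes egl-1, the BH3-only activator of cell death, rose by 3.98 ± 0.27 (SE), nuc-1 by 1.47, cps-6 by 1.45 and tir-1 by 1.19, and ced-2 fell by 1.57 on the log2 scale. Adjusted over the list alone these counts were the same, and 2 were lower without 1 h B. Of 37 genes of the adult mother or of sperm gsp-4 (0.65) and msp-63 (0.34) were higher, and 0 adjusted over the list alone, with 9 higher and 1 lower by limma at an unadjusted p under 0.05, and 4 higher and 3 lower past the threshold without 1 h B. The 11 lists not given a camera value so far had adjusted p from 0.11 for cilia and stress to 0.96 for endoderm.

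Of the 22548 probe sets 42.6% of the calls were rises with the deposited scaling. That share was 55.7% with arrays centred on the Affymetrix controls, 11.6% on the hybridisation controls and 2.81% on ribosomal protein genes, settings that moved the median difference of all probe sets from 0.09 to 0.20, -0.87 and -1.21, and centring on the array median moved it to -0.02. Smaller rises, those of mls-2, lam-1, ost-1, dgn-1, unc-95, noah-1, scrt-1, unc-130, tir-1, osm-12, dyf-2, msp-63, gsp-4 and cdk-2, turned to a value below 0 with ribosomal protein centring, while the means of the mesoderm regulators and of the maternal genes kept their sign in every setting tried. Where a gene's lower mean was under 3.22, the highest value of any background control, as for let-381 at 0 h and nos-2 at 4 h, the fold depends on values within background.

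**Figure D2:**
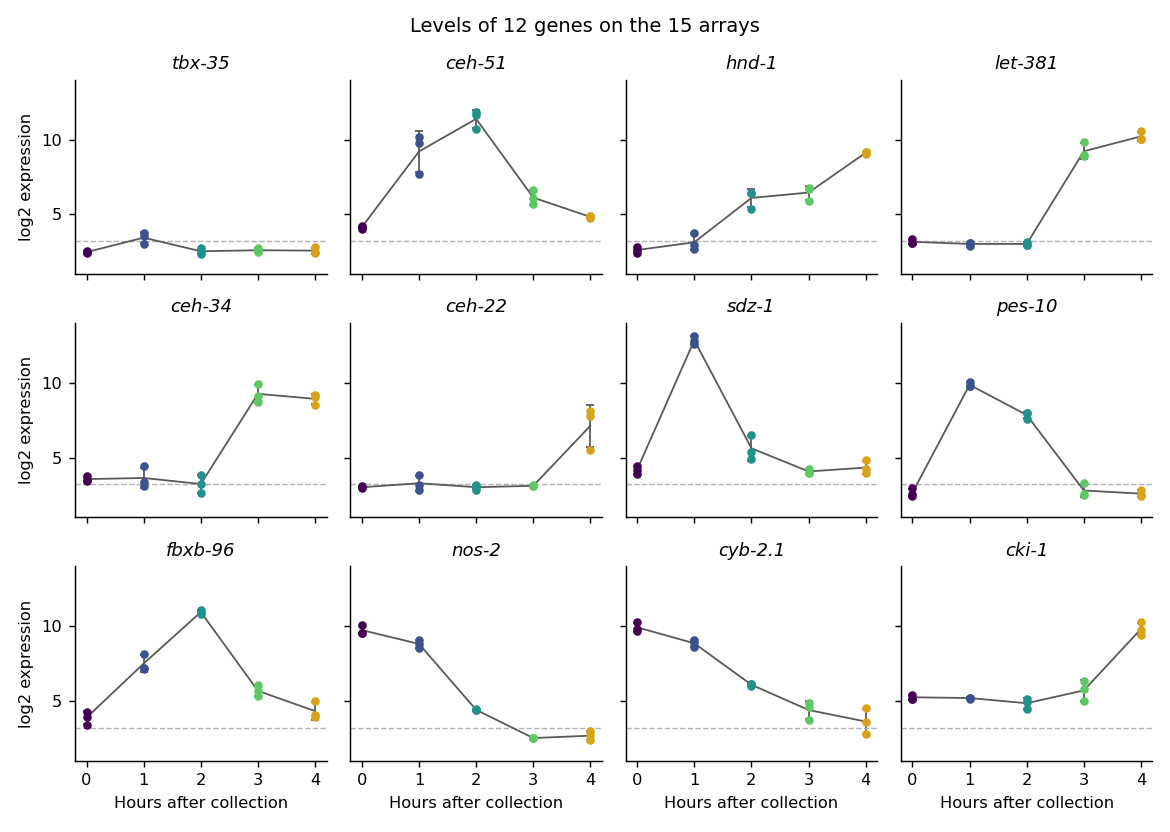
Log2 level of named genes at 0 to 4 h, with arrays as points and a line through the mean ± SD (n = 3 per time), and the highest background control value of 3.22 as a dashed line. let-381 lies near the dashed line until 2 h and at 9.22 and 10.2 at 3 h and 4 h, whereas nos-2 goes from 9.74 at 0 h to 2.68 at 4 h.

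**Figure D3:**
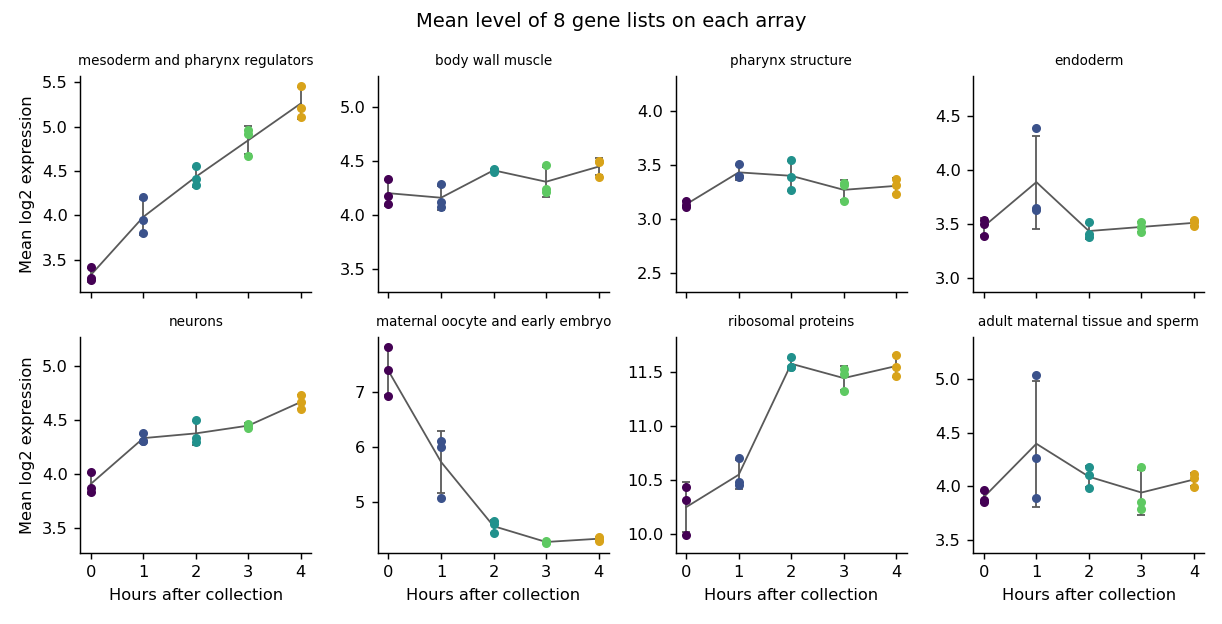
Mean log2 level of gene lists fixed in advance on each of the 15 arrays at 0 to 4 h. Arrays are points, with a line through the mean ± SD (n = 3 per time). Shown are the mesoderm and pharynx regulator, body wall muscle, pharynx structure, endoderm, neuron, maternal, ribosomal protein and adult or sperm lists. The maternal list goes from 7.38 at 0 h to 4.34 at 4 h. The ribosomal protein list goes from 10.2 to 11.6, a change set to 0 on average when arrays are centred on those genes.

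Between 0 h and 1 h 28 of 52 maternal genes fell, and 0 rose by limma, with 0 higher also at an unadjusted p under 0.05. sdz-1, named for its dependence on the maternal regulator SKN-1, rose from 4.19 to 12.9 (404-fold, 8.66 ± 0.34, SE), and pes-10, an early embryonic transcript, rose by 7.21 ± 0.22 from a 0 h mean of 2.66, which lies within background and leaves the size of the rise uncertain. Among mesoderm regulators ceh-51, an NK-2 homeobox gene of the MS lineage, rose by 5.06 ± 0.52, mls-2 by 1.05 and tbx-35, a T-box gene that specifies MS, by 0.97, 3 of 22 and the same number adjusted over the list alone. The endoderm regulators end-1 and end-3, GATA factors of the E lineage, rose by 2.25 ± 0.33 and 1.20 ± 0.22, 2 of 21 and the same number adjusted over the list alone. pgm-1, the oocyte surface genes egg-1 and egg-2, neg-1 and him-5 fell by 5.01, 4.77, 4.75, 4.63 and 4.35 on the log2 scale. limma called 743 probe sets higher and 1371 lower.

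Of 40 neuron genes the proneural genes ngn-1 (3.92 ± 0.30, SE) and hlh-3 (3.47 ± 0.26) and ceh-36 (1.82) rose, and also adjusted over the list alone. Of 15 Notch and AB lineage regulators ref-1 (1.90), ceh-36 and tbx-39 (0.65) rose, and 4 adjusted over the list alone. Of 22 pharynx structure genes abu-14 rose by 3.70 ± 0.45, also when adjusted over the list alone, while its other probe set changed by 0.022 (adjusted p = 0.94). Of 52 maternal genes 28 fell, and 33 adjusted over the list alone, among them pie-1, a repressor of transcription in the germ line, by 3.30 and oma-2 by 3.29 on the log2 scale. Without array 1 h B, which lay apart as described, 25 of the 52 fell. Of 26 epidermal genes ptr-2 and lin-26 fell by 3.15 and 1.88 on the log2 scale and fbn-1 rose by 0.82, with 1 higher and 3 lower adjusted over the list alone. Without 1 h B the fbn-1 call ended, and the ptr-2 probe set that should not cross-hybridise gave -0.29 (adjusted p = 0.67). tbx-9 of the C and D list (1 lower adjusted over the list alone) fell by 2.25 and cup-5 of the other mesoderm list (1 higher and 1 lower adjusted over the list alone) by 1.78 on the log2 scale. The chaperone genes hsp-1, hsp-4, hsp-60 and hsp-6 fell by 3.13, 2.81, 2.37 and 1.31, 4 of 14 and the same number adjusted over the list alone, and 3 fell without 1 h B.

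Of 18 apoptosis genes nuc-1, a nuclease of dying cells, rose by 2.26 and ced-6 and ced-2 fell by 1.42 and 1.14 on the log2 scale, with the same counts adjusted over the list alone. Of 62 ribosomal protein genes 10 rose, and 17 adjusted over the list alone, such as rps-13 by 1.03 and rpl-14 by 0.88, both of which came below 0 with arrays centred on the hybridisation controls. cdt-1 (0.67) was the called gene of 43 cell cycle genes, and limma called 0 of them adjusted over the list alone, with 2 higher and 4 lower at an unadjusted p under 0.05. limma called 0 of 38 body wall muscle, 0 of 14 basement membrane and 0 of 26 cilium genes, over all genes and over the list alone, against 3 higher and 1 lower, 0, and 2 higher at an unadjusted p under 0.05. Of 37 genes of the adult mother or of sperm 9 were higher, all genes of the major sperm protein family, and 10 adjusted over the list alone. msp-59 rose by 1.70 ± 0.42 and msp-19 by 1.69 ± 0.36, and members of this family are near-identical. Array 1 h B read 8.58 for vit-4 of the same list, and without that array 6 genes of the list were higher and 1 was lower. The share of rises among the calls was 35.1%, with 493 higher and 2499 lower when arrays were centred on ribosomal protein genes, and 6.38% on the hybridisation controls, where tbx-35, mls-2, fbn-1, tbx-39 and cdt-1 came below 0. Without 0 h C 899 probe sets were lower. Placing arrays by their time tags, or leaving out both arrays of conflicting tag, keeps only 1 h A at 1 h. No counts are given here for these settings.

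Between 1 h and 2 h 5 of 22 mesoderm and pharynx regulators rose and 2 fell, and of 52 maternal genes 10 fell and 1 rose. The bZIP gene zip-8 rose from 4.12 to 10.3 (6.21 ± 0.25, SE), grl-11 by 5.59 ± 0.28 and ceh-20, a Pbx homeobox gene, by 4.95 ± 0.43. Of 22 mesoderm regulators eya-1 (3.21 ± 0.31), hnd-1 (2.96 ± 0.33), fkh-2 (2.74), ceh-51 (2.18) and mls-2 (1.70) rose. med-1, a GATA factor that specifies MS and E, and tbx-35 fell by 1.05 and 0.91 on the log2 scale, and adjusted over the list alone 5 were higher and 3 lower. sdz-1 and sdz-31 fell by 7.23 and 6.09, and end-1 and end-3 by 2.12 and 1.21 on the log2 scale, 2 of 21 endoderm genes and the same number adjusted over the list alone. limma called 1354 probe sets higher and 733 lower.

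Of 62 ribosomal protein genes 51 rose, and 57 adjusted over the list alone, led by rpl-9 (2.71 ± 0.32, SE), rpl-11.2 (2.55) and rps-7 (2.19), and 46 rose without 1 h B. Of 52 maternal genes 10 fell, and 17 adjusted over the list alone, among them cey-2 by 4.81, nos-2 by 4.41 ± 0.17, cpg-2 by 4.30 and pos-1 by 4.25 on the log2 scale, and 18 fell without 1 h B. par-2, of the polarity proteins, rose by 1.04, while its probe set that should not cross-hybridise gave -0.30. Of 43 cell cycle genes 6 rose and 3 fell, with 11 and 4 adjusted over the list alone, such as icp-1 (3.01), cya-1 (2.36), cdk-4 (2.01) and knl-2 (1.94), while cyb-2.1, cyb-2.2 and rnr-2 fell by 2.77, 2.40 and 1.33 on the log2 scale. Of 18 apoptosis genes nuc-1 (3.82 ± 0.43), ced-9, a Bcl-2 homologue (2.96), ced-8 (2.2), tir-1 (1.57) and cps-6 (1.41) rose, also when adjusted over the list alone, and 2 fell without 1 h B. Of 40 neuron genes hlh-14 (4.28) and unc-119 (1.66) rose and hlh-3 and ngn-1 fell by 3.53 and 1.59 on the log2 scale, with the same counts adjusted over the list alone.

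The muscle attachment genes dim-1 (2.35), unc-112 (2.22) and atn-1 (1.82) rose, 3 of 38 body wall muscle genes and the same number adjusted over the list alone, and 2 of 38 without 1 h B. Of 14 basement membrane genes epi-1 rose by 4.28 ± 0.34, and of 26 epidermal genes dpy-17 by 2.78 and the GATA factor gene elt-1 by 1.95, each also when adjusted over the list alone, and 1 epidermal gene fell without 1 h B. elt-1 belongs to the C and D list as well, in which tbx-9 fell by 1.91 on the log2 scale, with 1 higher and 1 lower adjusted over the list alone. Of 15 Notch and AB lineage regulators tbx-43 (3.72 ± 0.38) and die-1 (1.47) rose and ref-1 and tbx-39 fell by 2.27 and 0.80 on the log2 scale, with 3 higher and 2 lower adjusted over the list alone. msp-31, msp-152 and msp-33 fell by 1.10, 0.66 and 0.65, 3 of 37 genes of the adult mother or of sperm and the same number adjusted over the list alone, and 2 were lower without 1 h B. limma called 0 of 22 pharynx structure, 0 of 12 other mesoderm, 0 of 26 cilium and 0 of 14 stress genes, over all genes and over the list alone, against 1 lower, 1 lower, 1 higher and 2 lower, and 1 lower at an unadjusted p under 0.05. Placed by time tags, or without both arrays of conflicting tag, 1 h keeps array A alone, so no counts are given here. The share of rises among the calls was 64.9%, 3.47% with arrays centred on ribosomal protein genes and 83% on the hybridisation controls.

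Between 2 h and 3 h 4 of 22 mesoderm and pharynx regulators rose and 3 fell, with no set test run for this step. The T-box gene tbx-7 rose by 7.06 ± 0.33 (133-fold, SE), let-381 by 6.20 ± 0.22, ceh-34 by 6.03 ± 0.39 and ceh-27, an NK-2 homeobox gene, by 5.94 ± 0.35. The insulin-like gene ins-2 rose by 4.44 ± 0.53. The F-box genes fbxb-22 and fbxb-96 fell by 5.78 and 5.27 on the log2 scale, tag-276 by 5.43, vet-1 by 5.36 and ceh-51 by 5.26. limma called 186 probe sets higher and 429 lower. Of 22 mesoderm regulators ceh-34, let-381, tbx-2 (1.77) and ceh-32 (1.56) rose and ceh-51, mls-2 and fkh-2 fell, the last 2 by 2.31 and 1.60 on the log2 scale, with 6 higher and 3 lower adjusted over the list alone.

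egl-1 rose by 3.39 ± 0.27 (SE) as 1 of 18 apoptosis genes, epi-1 by 1.43 as 1 of 14 basement membrane genes and ceh-13 by 0.96 as 1 of 11 regulators of the C and D lineages. Adjusted over the list alone the counts were 1 higher and 1 lower, 1 higher, and 2 higher and 2 lower. ngn-1 (of 40 neuron genes), tbx-43 (of 15 Notch and AB lineage regulators) and abu-14 (of 22 pharynx structure genes) fell by 2.48, 3.53 and 3.19 on the log2 scale. The counts adjusted over the list alone were 1 lower, 2 higher and 2 lower, and 1 higher and 1 lower. The other abu-14 probe set changed by -0.42 (adjusted p = 0.12). nos-2 and gna-2 fell by 1.89 and 1.85 as 2 of 52 maternal genes (3 adjusted over the list alone, 5 without 1 h B), and cyb-2.2, dpl-1 and cyb-2.1 by 1.99, 1.91 and 1.69 as 3 of 43 cell cycle genes (also 3 adjusted over the list alone). rpl-11.1 fell by 1.72, with 0 of 62 ribosomal protein genes called by limma adjusted over the list alone and 4 lower at an unadjusted p under 0.05. limma called 0 members of the body wall muscle, other mesoderm, endoderm, epidermis, cilium, stress and adult lists, against 2 higher and 2 lower, 1 higher, 0, 2 higher and 1 lower, 1 lower, 1 lower and 0 at an unadjusted p under 0.05. Adjusted over the list alone 2 body wall muscle genes were lower and 1 of other mesoderm was higher. Without 1 h B 1 body wall muscle gene, 2 Notch and AB regulators and 2 ribosomal protein genes were lower, and 1 gene each of pharynx structure and other mesoderm was higher. Without 2 h C 1.1e+02 (rounded to 2 digits) probe sets were higher, and with arrays placed by their time tags 1 was higher and 7 were lower. The share of rises among the calls was 30.2%, 43.1% with arrays centred on ribosomal protein genes and 7.91% on the hybridisation controls.

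Between 3 h and 4 h 129 probe sets were higher and 156 lower by limma, the fewest of the 4 steps. With arrays placed by their time tags 90 were higher and 58 lower, more than between 2 h and 3 h. ces-2 and ces-1, a bZIP and a Snail-family gene that control which cells die, rose by 5.13 ± 0.49 and 5.03 ± 0.19 (SE). hil-7, a histone H1-like gene, rose by 4.97 ± 0.48, the collagen gene col-118 by 4.40, the small heat shock gene hsp-12.2 by 4.39 and cki-1 by 4.11 ± 0.31. sdz-28 and btb-11 fell by 3.46 and 3.38 on the log2 scale. Of 22 mesoderm regulators ceh-22 (4.02 ± 0.50), hnd-1 (2.66) and fkh-2 (2.29) rose, and 5 adjusted over the list alone. Of 40 neuron genes lin-32 (2.56 ± 0.27), hlh-3 (1.8), unc-30 (1.76) and ngn-1 (1.55) rose, and 5 adjusted over the list alone.

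lam-3 rose by 3.86 ± 0.30 (SE) as 1 of 14 basement membrane genes, with 1 higher and 1 lower adjusted over the list alone, and ceh-13 by 2.54 ± 0.22 as 1 of 11 regulators of the C and D lineages, also adjusted over the list alone. nuc-1 fell by 2.93 on the log2 scale as 1 of 18 apoptosis genes, also adjusted over the list alone. cki-1 was the called gene of the 43 cell cycle genes, with 1 higher and 2 lower adjusted over the list alone. Without 1 h B 1 cell cycle gene was lower and 1 epidermal gene higher. limma called 0 members of the other 11 lists tested, over all genes and over the list alone. At an unadjusted p under 0.05 those lists held 4 higher body wall muscle genes, 1 higher and 1 lower of pharynx structure, 0 of other mesoderm, 1 higher of endoderm, 5 higher of epidermis, 2 higher and 1 lower of cilia, and 1 lower of Notch and AB regulators. They held 2 higher and 2 lower maternal genes, 2 higher stress genes, 2 higher adult or sperm genes, and 5 higher and 1 lower ribosomal protein genes. The share of rises among the calls was 45.3%, against 57.4% with arrays centred on the Affymetrix controls, 72.5% on the hybridisation controls and 32.1% on ribosomal protein genes.

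**Figure D4:**
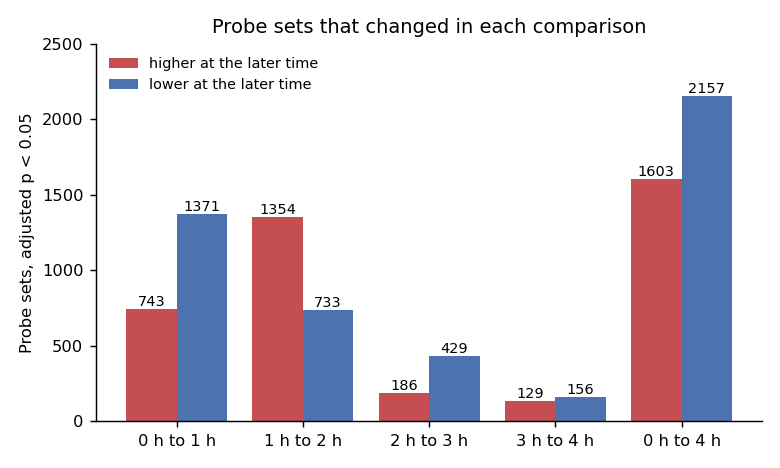
Number of probe sets higher or lower (limma, adjusted p under 0.05) in each comparison, of 22548 tested, with bars starting at 0. The counts go from 743 and 1371 for 1 h against 0 h to 129 and 156 for 4 h against 3 h.

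A further question was which transcripts were above 0 h at an intermediate time and lower again at 4 h. ceh-51 was 7.24 ± 0.52 (SE) above 0 h at 2 h and then fell by 6.56 on the log2 scale to 4 h, from 11.4 to 4.82. At 1 h sdz-1, pes-10 and sdz-31 were 8.66, 7.21 and 6.48 above 0 h, and changed by -8.52, -7.28 and -6.22 to 4 h. At 2 h fbxb-96 and vet-6, a very early transcript, were 7.06 and 6.63 above 0 h and fell by 6.62 and 6.41. At 3 h sdz-28 and btb-11 were 5.20 and 3.58 above 0 h and fell by 3.46 and 3.38. Their means were highest at 2 h (10.3 and 10.6), above those at 3 h (8.25 and 8.08). limma gave 370 such probe sets for 1 h, 518 for 2 h and 125 for 3 h (315, 438 and 110 genes), 699 for any of the 3 times. The mean was highest at the named time in 223, 444 and 28 of them. With arrays placed by their time tags, which keeps 1 h A as the only 1 h array, the 2 h and 3 h counts were 214 and 36. The counts at 1, 2 and 3 h were 134, 209 and 11 with arrays centred on the hybridisation controls. With treat at 1.5-fold they were 219, 289 and 49, and at an adjusted p under 0.01 the 3 h count was 68.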

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

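All tests in this part were chosen after the result was seen. The hybridisation controls, which enter no comparison with the deposited scaling, read 1.68 log2 units higher on array 1 h B than on the other 14 arrays on average, 11.70 against a mean of 10.02 and a highest other value of 11.099. That array also had the lowest correlation with arrays of its own time, 0.914.

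Array 1 h B stands apart from 1 h A and 1 h C, and its time tag reads 2 h. A 2 h sample on that array is argued against by its highest correlation with a 2 h array, 0.878, which lies below its lowest with the other 1 h arrays, 0.914. On the first principal component it lay at -21.8, between the other 1 h arrays (-52.5 and -54.6) and the 2 h arrays (32.6 to 41.9). On the second it lay at 76.8, beyond both. These values do not tell whether its embryos were older than those of the other 1 h arrays. Less sample RNA on the array may contribute, since added controls then read brighter, and their mean lay 1.68 above that of the other arrays. RNA of the adult gut, from the dissected mothers, is another candidate explanation: a list of adult gut genes, without those already seen high on that array, had a median 0.586 above the other 1 h arrays (20 of 27 genes higher; 10000 random lists matched on level had a median of 0.097, and the list lay at percentile 100 of them). Its most abundant gene there, gst-1, lay between the other 1 h arrays (8.74 against 8.70 on 1 h A and 9.35 on 1 h C), while clec-63 read 7.52 against 5.32 and 5.21 and the left-out vit-5 8.82 against 3.10 and 2.97; 16 of the 44 genes of the full list belong to the endoderm or adult list. A list of adult body wall genes treated alike had a median of 0.268 (percentile 94.4), so tissue beyond the gut stays open, and these explanations do not exclude each other.

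Array 1 h C carries a time tag of 3 h. Its highest correlation with a 3 h array was 0.882, below its 0.981 with 1 h A, which argues against a 3 h sample on it. No biological explanation was tested for either array.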

How the results depend on the processing

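Chosen only after the results were seen were the centring on hybridisation controls, the leaving out of array 1 h B for comparisons without 1 h and the list member counts without 1 h B; the other settings were planned. In all 22 settings run on the gene lists the mesoderm and pharynx regulators kept a mean above 0 and the maternal genes a mean below 0, both past limma's camera threshold. Where arrays were centred, the genes that camera compares a list with were shifted too, so passing there is weak support. A trended robust eBayes and the upper part of the probe sets by mean moved no count by over 1.5 times and ended no call of a list, though they ended 6 and 1 named gene calls, and the upper part gave no value for genes it removed. The mean of a gene's probe sets, run on the lists alone, ended no call of a list. Of 303 named gene comparisons 291 passed the threshold. Some named results kept their sign but lost their call. They numbered 81 with treat at 1.5-fold, 69 with hybridisation controls and 51 at an adjusted p under 0.01. They numbered 25 with ribosomal centring, 24 with the array median and 18 with Affymetrix controls. Changes of sign, counted apart and partly of results not called before, numbered 27 with hybridisation controls, 24 with ribosomal centring and 1 with the array median. Losses with the time tags as groups, or without the arrays of conflicting tag, rest partly on 1 h A alone and are not counted. Signal over background limits the rest: 48.1 to 58.4% of probe sets per array lay above the mark of 3.22, so a small or absent change of a gene near it may only be out of reach, as with the myo-3 value of -0.076 with arrays centred on the array median. The number of arrays, 3 per time, limits the precision.

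Grouped by the time tag, 2193 probe sets changed over time. Higher at 4 h than at 0 h were 1023, and 1.2e+02 (rounded to 2 digits) were higher and 228 lower at 1 h than at 0 h. At 2 h against 1 h limma called 0 higher and 1 lower (473 and 858 at an unadjusted p under 0.05), and at 3 h against 2 h 1 higher and 7 lower (648 and 635). At 4 h 58 were lower than at 3 h, and transient probe sets numbered 23, 214 and 36 at 1, 2 and 3 h. The cell cycle list had its mean of -0.54 with an adjusted p of 0.036 (0.014 to 0.95 over its 22 settings), vit-4 was -1.41 at 1 h against 0 h and msp-31 0.018 at 2 h against 1 h. Without the arrays of conflicting tag 493 were higher and 633 lower at 1 h, 763 higher at 2 h, and vit-4 was again -1.41. vit-4 was high on array 1 h B alone among the 1 h arrays, which shows the cause there. In both settings 1 h A is by construction the only 1 h array, so each count or value involving 1 h rests on it. A single array gives no spread at 1 h, so these counts cannot decide whether the 1 h results hold. No conclusion is drawn from them. With the tags as groups, 1 h B joins the 2 h arrays and 1 h C the 3 h arrays. The correlations argue against both placements. Array 1 h B reached 0.878 with a 2 h array and at least 0.914 with the other 1 h arrays. Array 1 h C reached 0.882 with a 3 h array and 0.981 with 1 h A. Whether this placement widened the shared spread and so changed the results without 1 h was not tested.

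Without probe sets that can cross-hybridise, fewer probe sets were tested. Changed over time were 2702, and for 4 h against 0 h 933 were higher and 1174 lower. The counts were 467 and 793 for 1 h against 0 h, 810 and 443 for 2 h against 1 h, and 85 higher for 4 h against 3 h. The means were 0.83 for C and D lineage regulators (adjusted p = 0.04, 0.04 to 0.63 over 22 settings), 0.13 for cell cycle and -0.36 for adult and sperm genes. Other probe sets of the genes then gave -0.056 for Y54F10AM.8 and 0.80 for ptr-2 at 4 h against 0 h, and -0.30 for par-2 at 2 h against 1 h. With array weights 1372 were higher at 1 h than at 0 h, 2056 higher and 1798 lower at 2 h than at 1 h, and 408 higher and 732 lower at 3 h than at 2 h, with vit-4 at -0.92; the cause was not tested.

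Centring on ribosomal protein genes lowers all other genes by construction in comparisons in which these rose on average, as for 4 h against 0 h, and raises them between 2 h and 3 h, where the mean of these genes was -0.13. Then 21537 probe sets changed over time, with 583 higher and 20197 lower for 4 h against 0 h, 493 and 2499 for 1 h against 0 h, 667 and 18560 for 2 h against 1 h, and 309 higher for 3 h against 2 h. List means were -1.06 for body wall muscle, -1.14 for pharynx structure, -0.43 for basement membrane, -1.28 for endoderm, -1.12 for epidermis, -0.55 for neurons, -1.08 for cilia, -1.09 for C and D lineage regulators, -1.11 for Notch and AB lineage regulators, -1.04 for apoptosis (camera adjusted p = 0.01, 0.01 to 0.96 over 22 settings) and -1.15 for adult and sperm genes. For 4 h against 0 h mls-2 was -0.018, hlh-1 -0.59, unc-120 -0.55, unc-95 -0.83, myo-3 -1.27, unc-54 -1.03, myo-2 -1.12, ost-1 -0.75, lam-1 -0.65, dgn-1 -0.57, tir-1 -0.12 and noah-1 -0.40. There scrt-1 was -0.56, unc-130 -0.13, osm-12 -0.84, dyf-2 -0.48, msp-63 -0.97, gsp-4 -0.66, mex-1 -0.29, lit-1 -0.82, pal-1 -0.69, elt-2 -0.82 and cdk-2 -0.65, and zyg-1 was -0.08 at 2 h against 1 h.

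Centring on hybridisation controls also moves all genes of an array alike, and these controls were brightest on 1 h B. Higher at 4 h than at 0 h were 313. The higher and lower counts were 181 and 2658 for 1 h against 0 h, 701 and 144 for 2 h against 1 h, 20 and 233 for 3 h against 2 h, and 37 and 14 for 4 h against 3 h, with 134, 209 and 11 transient probe sets at 1, 2 and 3 h. List means were -0.71 for body wall muscle, -0.79 for pharynx structure, -0.083 for basement membrane, -0.93 for endoderm, -0.77 for epidermis, -0.20 for neurons, -0.73 for cilia, -0.74 for C and D lineage regulators, -0.76 for Notch and AB lineage regulators, -0.69 for apoptosis and -0.80 for adult and sperm genes. For 4 h against 0 h hlh-1 was -0.24, unc-120 -0.20, unc-95 -0.48, myo-3 -0.92, unc-54 -0.68, myo-2 -0.77, ost-1 -0.40, lam-1 -0.30, dgn-1 -0.22, noah-1 -0.049 and scrt-1 -0.21. There osm-12 was -0.49, dyf-2 -0.13, msp-63 -0.62, gsp-4 -0.31, lit-1 -0.47, pal-1 -0.34, elt-2 -0.47 and cdk-2 -0.30. For 1 h against 0 h tbx-35 was -0.22, mls-2 -0.13, vit-4 -0.73, fbn-1 -0.37, tbx-39 -0.53, cdt-1 -0.51, rps-13 -0.15 and rpl-14 -0.31.

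Centring on Affymetrix controls gave 1.2e+02 (rounded to 2 digits) probe sets higher at 3 h than at 2 h and 100 lower at 4 h than at 3 h, a mean of 0.025 for other mesoderm and -0.44 for cell cycle (adjusted p = 0.014, 0.014 to 0.95 over 22 settings). Centring on the array median gave -0.084 for the endoderm list and -0.076 for myo-3. With treat at 1.5-fold, a stricter test by construction, the higher and lower counts were 797 and 1281 for 4 h against 0 h, 372 and 582 for 1 h against 0 h, 626 and 323 for 2 h against 1 h, 54 and 224 for 3 h against 2 h, and 53 and 56 for 4 h against 3 h, with 219, 289 and 49 transient probe sets. At an adjusted p under 0.01, also stricter by construction, 1042 were higher for 4 h against 0 h, 473 higher and 772 lower for 1 h against 0 h, 839 and 426 for 2 h against 1 h, 92 higher for 3 h against 2 h, and 72 and 83 for 4 h against 3 h, with 68 transient at 3 h. The basement membrane list, at a mean of 0.88, had an adjusted p of 0.019 and missed that threshold, and with an estimated correlation it had 0.21 (0.0035 to 0.21 over 22 settings). The neuron list, at 0.76, also had 0.21 there (5.7e-06 to 0.21).

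With each array left out in turn, the probe sets lower at 1 h than at 0 h ran from 899 (without 0 h C) to 1483 and those higher at 3 h than at 2 h from 1.1e+02 (rounded to 2 digits, without 2 h C) to 221. The cell cycle mean ran from -0.72 to -0.39, endoderm from -0.01 to 0.064, myo-3 from -0.029 to 0.11 and pal-1 from -0.091 to 1.26 for 4 h against 0 h, and vit-4 from -1.37 (without 1 h B) to 1.39 for 1 h against 0 h. Without 1 h B, limma again called, with the same sign, 99.1% of the probe sets called for 4 h against 0 h, 72.6% for 1 h against 0 h, 80.6% for 2 h against 1 h, 98.5% for 3 h against 2 h and 96.1% for 4 h against 3 h.

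With the replicate letter as a block 4359 probe sets changed over time, and 1536 were higher and 2119 lower for 4 h against 0 h. The counts were 702 and 1304, 1317 and 703, 184 and 407, and 115 and 132 for the steps in order, and 348, 485 and 107 probe sets were transient. The block changed no call of a list and ended 11 of the named gene calls. Same-letter arrays did not deviate together: the mean correlation of their deviations was -0.003, 7 of 30 pairs lay above 0.1, and 3 of 15 arrays were closest to one of their own letter.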

Other observations

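The ribosomal tests and those of other splits were set before their results were seen, and the F-box family was chosen after its members were seen among the named genes. F-box genes, whose products pick proteins for degradation, were at their highest mean level at 2 h, while the median difference over the family was 0.15 for 2 h against 0 h and -0.044 for 4 h against 2 h. Over 310 such genes the mean was 3.15 ± 0.03 at 0 h, 3.88 ± 0.02 at 1 h, 4.44 ± 0.04 at 2 h, 3.78 ± 0.04 at 3 h and 3.55 ± 0.02 at 4 h (log2, SD over 3 arrays). The 0 h mean lies below 3.22, the highest background control value, and the SD is that of a family average, not of single genes. By limma 108 of them rose between 0 h and 2 h and 10 fell, and 86 fell between 2 h and 4 h and 8 rose. Of the 310, which are the genes named fbxa, fbxb or fbxc, 83 (26.8%) were above 0 h at 2 h and lower again at 4 h, against 2.11% of other genes. Most of the 83 were fbxb genes, and the fbxa genes among them were fbxa-103, fbxa-120 and fbxa-150. Shares for each of these name groups were not computed. With arrays centred on ribosomal protein genes, Affymetrix controls, array medians or hybridisation controls 72, 78, 82 and 58 of the 310 did so, against 1.34%, 1.72%, 2.09% and 0.761% of other genes.

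Proteasome subunit genes went the other way from ribosomal protein genes. Of 33, 25 fell between 0 h and 4 h by limma, with a median of -2.48, and the mean level went from 9.41 ± 0.12 at 0 h to 6.82 ± 0.46 at 4 h (log2, SD over 3 arrays). pas-5 and pas-3, subunits of the core particle, fell by 3.06 and 2.74 on the log2 scale. The median stayed below 0 in all 4 scalings tried, from -3.79 to -2.38.

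A hypothesis is that F-box genes are over-represented among transcripts that are high at 2 h and lower at 4 h. A one-sided Fisher exact test gave p = 1.5e-61, with genes and not arrays as the unit, and genes of a family are not independent. Close copies that share probes could produce such a count, but without probe sets that can cross-hybridise 71 of 279 F-box genes were in it and the Fisher exact test gave p = 1.4e-52, which argues against that as the whole cause. The family was picked from these same data, so this remains a hypothesis, and no other gene family was tested for it.

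The rise of ribosomal protein genes, a median of 1.43, could come from a normalization that lifts bright genes alike. The highest median of 10000 lists matched on mean level was 0.707, which argues against it. A loss of maternal RNA could also lift every remaining abundant housekeeping gene alike. The proteasome genes, chosen to test this, had a median of -2.48 with an interquartile range of 1.14. They fell themselves, from a mean level of 9.41 at 0 h to 6.82 at 4 h, so they cannot show whether retained transcripts gain share. Their mean level of 7.85 also lies below the 11.07 of the ribosomal protein genes, and this explanation stays open. With a scaling on the ribosomal protein genes themselves their rise is 0 by construction, so an increase per embryo cannot be read from these values, and a biological change with time stays open and untested.

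In 1 of 100 splits of the 15 arrays into 5 groups of 3, the real one, as many as 4630 probe sets passed the F test, and the highest other split gave 1318, so chance can be excluded there. For single comparisons 10 splits are too few for a share under 0.05. As many probe sets as in the real split came in 1 of 10 splits each time, with real counts of 3760, 2114, 2087, 615 and 285 for 4 h against 0 h and the steps in order, and highest other counts of 0, 5, 0, 4 and 1 by limma. Lists past the camera threshold were as many as the real 5 in 3 of 10 splits, with a highest other of 6. Set in advance for chance were as many lists in at least 2 of 10 splits, which was met. In each other split the groups hold unequal numbers of 0 h arrays, so part of the time difference remains in it. The test therefore cannot decide, and chance stays open for the number of lists. Those splits too are too few for a share under 0.05. For transcripts above 0 h at 1, 2 or 3 h and lower at 4 h, 3, 2 and 2 of 100 splits of 9 arrays reached the real 370, 518 and 125. Nearly all other splits mix arrays of different times in a group, which widens the spread and leaves few calls (second highest other for 2 h: 0). Such low shares show that the times differ, but cannot decide whether a rise and fall is beyond chance. The highest other splits gave 997, 1485 and 1764, and each of these had the 0 h arrays together as its middle group, which points to the distance of the 0 h arrays from all others.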
